A study of Mus musculus with 10 samples.

How the data were processed

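RNA from the ventricles of 10 mice was measured, 1 array per mouse, with 5 mice injected with tamoxifen (50 mg/kg per day on 2 days, from a stock of 10 mg/ml in oil) and 5 injected with oil alone at 2 months of age; all were sampled 1 month later, at 3 months. Per the labels' protocols, complementary DNA was made from 450 ng of total RNA, labelled with biotin and hybridised to an Affymetrix mouse gene array. The deposited values are log2 signals that the authors made with RMA in Affymetrix Expression Console 1.1, per the submitters' processing notes; RMA corrects the background, normalizes the arrays to each other and summarises the probes of each probe set. They carry no detection call, and intensities of single probes were not used here. The deposited log2 columns had medians from 7.18 to 7.31, and no array was a copy of another.

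The value table held 35556 probe sets. Through the platform annotation, 21789 had 1 gene symbol, 1621 had several and 12146 had none. Symbols were checked through the Entrez identifier against a RefSeq gene table of assembly GRCm38.p6, used for names only; 0 symbols had to be updated and 91 probe sets had an identifier outside that table. Genes were named only from probe sets with 1 symbol. For the 998 genes with more than 1 probe set, the one with the highest mean was used. The dimmest 30% of these probe sets by their mean over all arrays (log2 cutoff 6.55) were left out, which removed 6069 genes and left 13870. A probe set can also bind transcripts of near-identical copies and pseudogenes, which respiratory chain genes have, and this was not separated here.

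Groups were taken from the labels. The comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariate, two-sided) and adjusted with Benjamini-Hochberg over all tested genes, with a threshold of 0.05. Gene lists were tested with limma's camera at an inter-gene correlation of 0.01, two-sided, adjusted over 45 lists. Lists with fewer than 3 tested members were left out: messenger RNAs from mitochondrial DNA, granulocytes, erythroid cells and sex-linked genes. Beside camera stand camera with an estimated correlation and fry, which tests whether a list's genes move one way on balance. By camera 25 lists passed, by camera with an estimated correlation 8 and by fry 28. The estimated correlation was 0.35 in the oxidative phosphorylation list and 0.59 in the macrophage markers, far above 0.01. The p-values of camera at 0.01 can therefore be much too small. Calls adjusted over the list alone use the same p-values with Benjamini-Hochberg within the list. List means were compared with each other by an exact two-sided permutation test of the arrays' score differences. The median residual SD was 0.0942 on the log2 scale.

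The test of the comparison, the 45 lists and their tests, the alternatives below except the final 2, and the rule for named genes were set before the data were examined. The 11 comparisons between lists and the further gene families with their tests were chosen after seeing the data. So were the tests of explanations other than chance splits, that of the hour of collection before its own result was seen. The adjusted p of the further families covers those families alone, not the 45 lists or the search that led to them. The quantile normalization used against a shift of whole arrays was itself set before, and only its use as that test came later. The rule names the PGC-1 family, the 15 highest rises and 15 deepest falls among genes past the threshold whose groups did not overlap (predicted genes skipped), up to 4 tested members with the smallest p of each list, and Mfn1, Mfn2, Opa1 and Dnm1l. Not all genes this rule allows are named. The code was tested on simulated data for the same 13870 genes, each drawn independently of the others, with 200 changed genes. For the comparison of tamoxifen with vehicle it recovered 69.1% of changes of 0.3 on the log2 scale, 98.5% of changes of 1.5-fold and 100% of changes of 1. Of 187 calls, 4.81% were false. Real genes vary together, and 3059 passed the threshold, so these shares check the code and need not hold for the real arrays. Alternatives were the replicate number as a block, a trended and robust prior, array weights, quantile normalization, centring on the median, no filter or a 50% filter on dim probe sets, the mean of a gene's probe sets, probe sets of several genes kept, each array left out in turn, both other list tests, and, chosen after seeing the data, 2 arrays left out together and the immediate early family without 5 members. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.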

Results

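Gene expression was measured in the ventricles of 10 mice, with 1 Affymetrix mouse gene array per mouse. Per the labels, all 10 mice lacked PGC-1α (gene Ppargc1a). The source names give both groups floxed alleles of PGC-1β (gene Ppargc1b) and MerCre, a Cre recombinase that tamoxifen switches on. The titles and the design text name neither for the 5 vehicle-labelled mice. The source names were followed, and under the titles the groups would differ in genotype as well as in tamoxifen. Both proteins are transcriptional coactivators known for raising genes of mitochondrial respiration. At 2 months of age, 5 mice were given tamoxifen on 2 days in a row and 5 were given the oil without it, and the hearts were taken 1 month afterwards. The arrays are called tamoxifen-labelled and vehicle-labelled here, and each log2 fold change is the former minus the latter, with its SE after ±. The comparison asks what changes in an adult ventricle without PGC-1α when PGC-1β is removed as well. The platform gave signals for 19939 genes, of which 13870 were bright enough to be tested. The number of arrays, 5 per group, limits the precision.

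Genes of mitochondrial respiration were lower in the tamoxifen-labelled arrays. Of 88 measured nuclear genes of oxidative phosphorylation, 84 fell, and the mean over all 88 was 1.56-fold lower. All 19 measured genes of the TCA cycle and pyruvate oxidation fell, with a mean 1.55-fold lower. Genes of the heart failure and fetal programme went the other way, with 16 of 24 higher, 0 lower and a mean log2 fold change of 0.44. The highest rise of a named gene was that of Gamt, an enzyme of creatine synthesis, at 3.82-fold (log2 8.92 ± 0.028 to 10.86 ± 0.15, SD, n = 5 per group).

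The targeted gene went against its label. Ppargc1b was read by 1 probe set (10459193), with log2 signals of 9.76, 9.69, 9.82, 9.65 and 9.90 in the vehicle-labelled arrays 1 to 5 and 9.93, 10.15, 10.11, 9.93 and 10.03 in the tamoxifen-labelled arrays 1 to 5. It rose by 0.27 ± 0.061 (SE; limma adjusted p = 0.00518), higher in 5 of 5 tamoxifen-labelled arrays than in any vehicle-labelled one. Where this probe set lies relative to the deleted exons is not given in the sources used here, and a probe set outside them would check nothing. Every direction below therefore rests on the labels alone. Ppargc1a, labelled as deleted in both groups, read 10.81 ± 0.14 and 11.20 ± 0.23 (SD, n = 5), a rise of 0.39 ± 0.095 with an adjusted p of 0.00797, and the same limit holds for it. The related coactivator gene Pprc1 rose by 0.19 ± 0.067 (adjusted p = 0.0472), a call that was lost without vehicle array 1, 3, 4 or 5 or tamoxifen array 1, 2, 4 or 5, with adjusted p from 0.0534 to 0.108 (0.00580 to 0.172 over all alternatives). As a list, these 3 genes passed the set test (adjusted p = 0.0362, adjusted p = 0.277 with an estimated correlation), but not without vehicle array 4 (adjusted p = 0.0501) or tamoxifen array 3 (adjusted p = 0.0547), with a range of 0.00423 to 0.277 over all alternatives.

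Of the 13870 genes, 1906 were higher and 1153 lower at an adjusted p of 0.05, and 71 and 150 of these differed by 1.5-fold or more. In 16.7% of the genes the 5 values of one group all lay on one side of the other 5, against 0.794% expected by chance. The first principal component, with 48.8% of the variance, separated the groups. The tamoxifen-labelled array 2 stood apart, with a median signal of 7.31 against 7.18 to 7.24 in the other 9 arrays. Higher genes made up 62.3% of the calls with all arrays, 49.7% without tamoxifen array 2 and 51.8% with arrays weighted by their quality. Without tamoxifen array 2, 1646 genes were lower. Leaving out vehicle array 4 together with it, an alternative chosen after seeing the data, gave 46.3%.

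**Figure D1:**
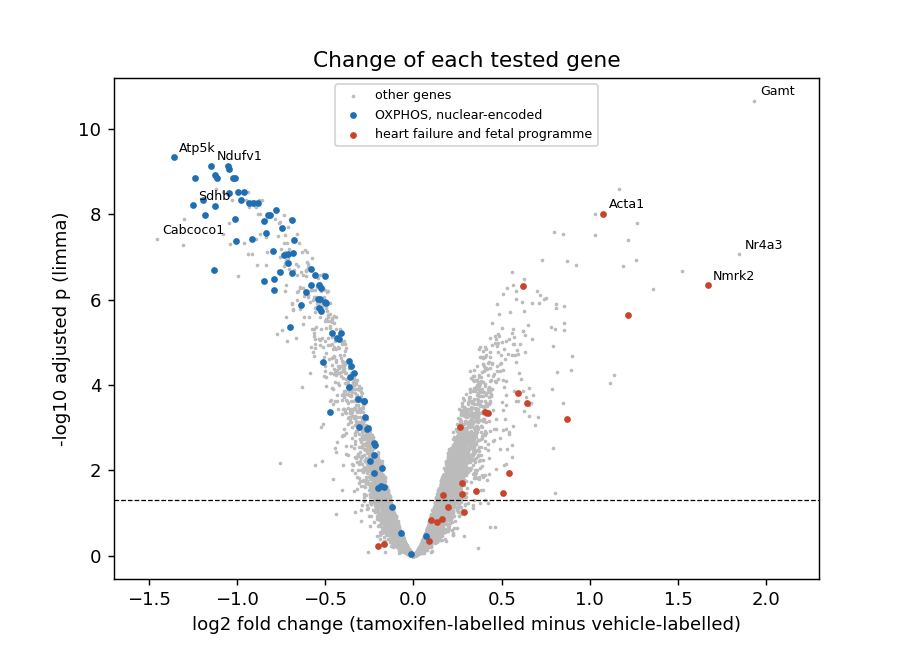
Each point is 1 of 13870 tested genes, placed by its log2 fold change, tamoxifen-labelled minus vehicle-labelled arrays (n = 5 each), and by the −log10 of its limma adjusted p, with the dashed line at 0.05. Most nuclear-encoded oxidative phosphorylation genes (blue, 84 of 88 called lower) lie in the left arm, among many other genes (1153 called lower in all). Most heart failure and fetal genes (red, 16 of 24 called higher) lie on the right.

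Every respiratory complex took part in the fall. In complex I, 37 of 38 genes fell (mean log2 fold change -0.67), among them Ndufa5 by 1.24 ± 0.061, Ndufb8 by 1.20 ± 0.067, Ndufb10 by 1.13 ± 0.093, Ndufa9 by 1.05 ± 0.048 and the NADH-binding subunit Ndufv1, from 12.46 ± 0.017 to 11.32 ± 0.090 (SD, n = 5). In complexes II and III with cytochrome c, 15 of 15 fell (mean -0.86). Here the succinate dehydrogenase subunits Sdhb and Sdhd fell by 1.25 ± 0.074 and 1.18 ± 0.074, and the complex III subunits Cyc1, Uqcrfs1 and Uqcrq fell by 1.13, 1.13 and 1.05. In complex IV, 17 of 19 fell (mean -0.45), with Cox5b at -1.01 ± 0.065 and Cox4i1 at -0.98 ± 0.056. In complex V, 15 of 16 fell (mean -0.60), led by the ATP synthase genes Atp5k at -1.36 ± 0.057 and Atp5o at -1.11 ± 0.056. The list of all complexes passed the set test (camera adjusted p = 5.34e-78, adjusted p = 0.0205 with an estimated correlation), as did each complex, with adjusted p of 0.0205 for I, II with III and V and 0.0253 for IV with an estimated correlation. Adjusted over the list alone, 85 genes of all complexes were lower. The 4 genes not called, named after their values were seen, were Ndufaf2 (-0.012), Cox8b (-0.070), Cox6a2 (-0.12) and Atpif1 (0.072). Cox6a2 passed without tamoxifen array 2 (adjusted p = 0.0146), and both Cox6a2 and Cox8b passed after quantile normalization (adjusted p = 0.0111 and 0.0313). Over all alternatives their adjusted p ranged from 0.00474 to 0.145 and from 0.0313 to 0.438. The mean of complexes II and III lay below that of complex IV by −0.41 ± 0.024 (SE, exact permutation p = 0.00794). That p is the smallest that 5 against 5 arrays can give (adjusted p = 0.0097 over 11 list comparisons chosen after the lists were seen). This pair has the lowest and the highest mean of the complexes. Every other pair of complexes gave the same p, even complex I against V with a difference of -0.069. In these and the later list comparison, SE and p measure the spread between arrays, not between genes. The SD over genes was 0.31 in complexes II and III and 0.30 in complex IV. The complex IV list also holds assembly factors, so the difference need not be one between subunits.

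Enzymes that feed the respiratory chain fell too. The TCA cycle and pyruvate oxidation list passed the set test at an adjusted p of 1.58e-29 and of 0.0205 with an estimated correlation, with 19 of 19 lower adjusted over the list alone. Dlat, of the pyruvate dehydrogenase complex, fell by 1.12 ± 0.059, Dlst, of the 2-oxoglutarate dehydrogenase complex, by 1.08 ± 0.058, and Idh3b by 0.95 ± 0.054. Of 19 genes that break down branched-chain amino acids, 18 fell (mean -0.53; 18 adjusted over the list alone, list adjusted p = 1.52e-25, and 0.0205 with an estimated correlation). They included the phosphatase gene Ppm1k (-1.08 ± 0.074), Dbt (-0.72) and Bcat2 (-0.63). Fatty acid oxidation genes fell less, 19 of 26 over all genes and 19 adjusted over the list alone, with a mean of -0.24. Their set test gave an adjusted p of 3.73e-12, and an adjusted p of 0.135 with an estimated correlation. Echs1 (-0.84 ± 0.054) and Acadvl (-0.68 ± 0.048) were among those that fell. The oxidative phosphorylation mean lay below the fatty acid oxidation mean by −0.40 ± 0.034 (SE; exact permutation p = 0.00794, adjusted p = 0.0097 over the same 11 comparisons).

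Of 5 genes of ketone body use, Oxct1 (-0.49), Bdh1 (-0.74) and 3 in all fell, and the transporter gene Slc16a1 rose by 0.21, as 1 of 2 that rose (3 and 2 adjusted over the list alone; set adjusted p = 0.0366). That adjusted p was 0.345 with an estimated correlation and 0.0820 without tamoxifen array 2, and ranged from 0.000355 to 0.345 over all alternatives. Of 18 PPAR target genes, 5 fell (6 adjusted over the list alone, mean -0.10, adjusted p = 0.0194), among them the lipase gene Pnpla2 (-0.65). The PPAR list gave an adjusted p of 0.423 with an estimated correlation, 0.0751 without tamoxifen array 2 and 0.0548 without vehicle array 5 (0.00488 to 0.423 over all alternatives). Of 16 energy carriers, 11 fell and 3 rose (11 and 3 adjusted over the list alone, list adjusted p = 1.10e-05, adjusted p = 0.0596 with an estimated correlation). The mitochondrial carrier gene Slc25a11 fell by 0.75, while the creatine transporter gene Slc6a8 rose by 0.49 ± 0.055 and the creatine kinase gene Ckm by 0.20 ± 0.044. Glycolysis genes did not pass as a list (adjusted p = 0.349): 7 of 23 rose, including Pgam2 (0.57) and Eno3 (0.32), and 4 fell, including Pgam1 (-0.52), with 9 and 5 adjusted over the list alone. By fry the glycolysis list passed (adjusted p = 0.0142, range 0.0142 to 0.719 over all alternatives).

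Genes that shape and build mitochondria fell in part. Of 18 genes of mitochondrial dynamics, 12 fell (12 adjusted over the list alone, mean -0.33, adjusted p = 2.82e-11), and the set test gave an adjusted p of 0.0655 with an estimated correlation. Opa1, which fuses inner membranes, fell by 0.61 ± 0.051, the outer-membrane fusion gene Mfn1 by 0.34 ± 0.050, the fission gene Dnm1l by 0.42 ± 0.056, Mtfp1 by 1.04 ± 0.076 and Samm50 by 0.73 ± 0.046. Mfn2 was not called, at 12.50 ± 0.017 and 12.56 ± 0.060 (SD, n = 5, adjusted p = 0.425). Of 73 mitochondrial ribosomal genes, 47 fell (48 lower and 1 higher adjusted over the list alone, mean -0.28, adjusted p = 5.75e-26), among them Mrpl12 (-0.90), and the adjusted p was 0.0510 with an estimated correlation. Of 19 genes of mitochondrial DNA maintenance and transcription, 10 fell (10 adjusted over the list alone, list adjusted p = 3.86e-07, adjusted p = 0.206 with an estimated correlation), including Lrpprc (-0.82) and the transcription elongation factor gene Tefm (-0.70). Of 24 import genes, 12 fell and 2 rose (12 and 2 adjusted over the list alone, list adjusted p = 2.61e-08, adjusted p = 0.135 with an estimated correlation), with Tomm40l at -0.90 and Timm23 at -0.60. Of 15 mitochondrial chaperones and proteases, 10 fell (10 adjusted over the list alone, list adjusted p = 2.54e-08, adjusted p = 0.135 with an estimated correlation), with the chaperone gene Hspa9 at -0.64 and the protease gene Clpp at -0.47. Messenger RNAs made from mitochondrial DNA had 0 named probe sets among those tested and were not analysed here.

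**Figure D2:**
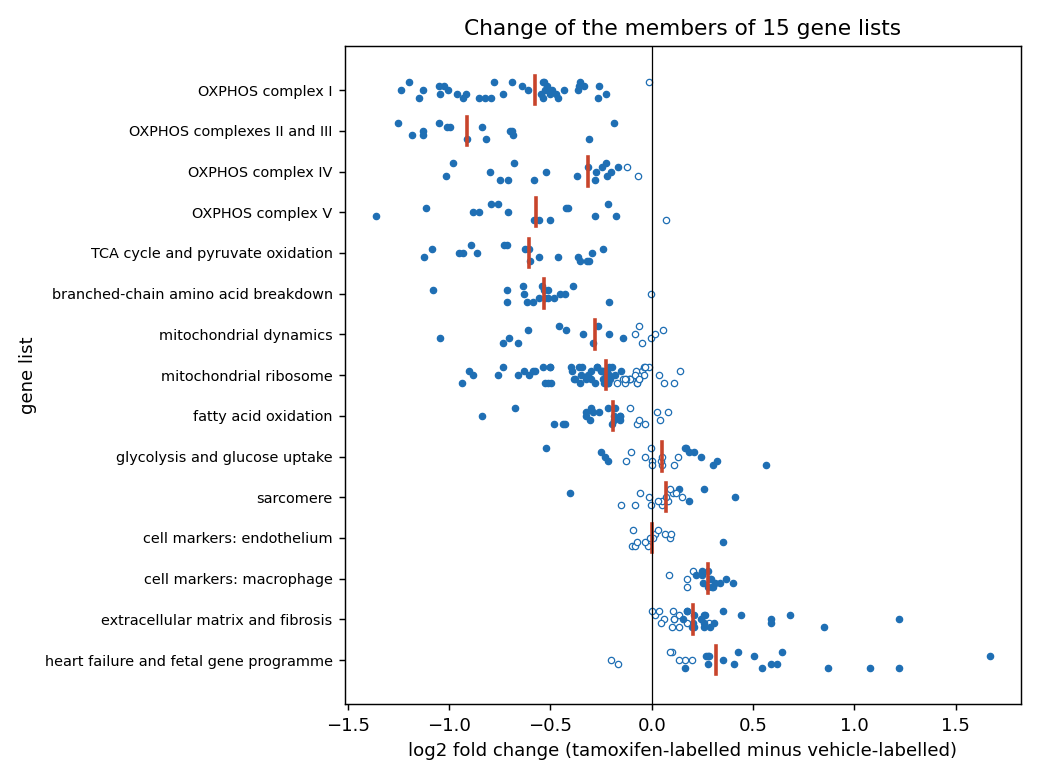
Each point is 1 gene of 1 of 15 gene lists, placed by its log2 fold change, tamoxifen-labelled minus vehicle-labelled arrays (n = 5 each), with filled points past an adjusted p of 0.05 and a red bar at the list's median. The medians run from -0.91 in complexes II and III to 0.32 in the heart failure and fetal programme, with the sarcomere at 0.072 and the endothelium at -0.0010.

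Antioxidant genes did not pass as a list with all arrays (adjusted p = 0.0538), with 5 of 23 lower and 2 higher (7 and 3 adjusted over the list alone). The list passed without vehicle array 3 (adjusted p = 0.0339) or tamoxifen array 1, 4 or 5 (adjusted p = 0.0459, 0.0338 and 0.0481), and its adjusted p ranged from 0.00287 to 0.487 over all alternatives. Its mitochondrial members Txn2 and Sod2 fell by 0.78 ± 0.048 and 0.58 ± 0.045. Phospholipid and cardiolipin synthesis did not pass (adjusted p = 0.767; 3 of 19 higher and 2 lower, 4 and 2 adjusted over the list alone), with Lpin1 at 0.32 and the cardiolipin acyltransferase gene Taz at -0.37. Of 21 metabolic transcription factors, 6 fell and 1 rose (6 and 1 adjusted over the list alone, list adjusted p = 0.190). The nuclear receptor gene Esrra fell by 0.42 ± 0.057 and Rxrg rose by 0.39 ± 0.048. In the stress response of the ATF4 type, 9 of 26 rose and 1 fell (9 and 2 adjusted over the list alone, list adjusted p = 0.133), with the transcription factor gene Atf3 at 0.66 and the serine synthesis gene Psat1 at 0.49. This list passed without the filter on dim probe sets (adjusted p = 0.0264) and by fry (0.0261), with a range of 0.0261 to 0.585 over all alternatives. Autophagy genes did not pass as a list (adjusted p = 0.190; 4 of 22 higher, 0 adjusted over the list alone), except without the filter (adjusted p = 0.0493, range 0.0493 to 0.742 over all alternatives). Proteasome genes did (adjusted p = 0.0132; mean 0.087; 10 of 31 higher and 12 adjusted over the list alone), with Psmd6 at 0.27, and the adjusted p was 0.605 with an estimated correlation.

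Genes known to rise in a stressed ventricle rose in the tamoxifen-labelled arrays. The heart failure and fetal programme passed the set test (adjusted p = 3.20e-09, adjusted p = 0.0258 with an estimated correlation), with 18 of 24 higher adjusted over the list alone. The nicotinamide riboside kinase gene Nmrk2 rose by 1.67 ± 0.15, Timp1, an inhibitor of matrix proteases, by 1.22 ± 0.12, skeletal alpha-actin Acta1 by 1.08 ± 0.067, Fhl1 by 0.62 ± 0.055, Postn by 0.59 ± 0.089 and the natriuretic peptide gene Nppa by 0.42 ± 0.072. In the same arrays 14 of 18 macrophage markers rose (mean 0.26, adjusted p = 0.285 with an estimated correlation) and 8 of 15 fibroblast markers rose (mean 0.16, adjusted p = 0.373 with an estimated correlation). Matrix genes such as Timp1 and Postn are also made by those cells. Adult sarcomere genes did not pass as a list (mean 0.054, median 0.072, adjusted p = 0.189), with 4 of 19 higher, among them Nexn (0.41), and 1 lower, Tcap (-0.40; 5 and 2 adjusted over the list alone). The sarcomere list did pass, as higher, with a trended and robust prior (adjusted p = 0.0471), without the filter on dim probe sets (0.0490) and by fry (0.00233), with a range of 0.00233 to 0.547 over all alternatives. Calcium handling and ion channel genes went both ways (adjusted p = 0.239; 5 of 30 higher and 9 lower, 5 and 11 adjusted over the list alone), with the sodium channel subunit gene Scn4b at 0.74 ± 0.070 and the potassium channel gene Kcnj3 at -0.57 ± 0.070.

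Several genes with wide changes lay outside these lists. Besides Gamt, rises were seen for the transcription factor genes Nr4a3 (3.60-fold; 1.85 ± 0.14), Egr1 (2.56-fold; 1.36 ± 0.12) and Nr4a1 (2.16-fold; 1.11 ± 0.16), for Bex1 (2.88-fold), Cnksr1 (2.41-fold) and the water channel gene Aqp8 (2.40-fold). Lgi2 rose 2.32-fold, the potassium channel subunit gene Kcne1 2.28-fold, Efhd2 2.24-fold, the relaxin receptor gene Rxfp1 2.20-fold and Akip1 2.04-fold. Cabcoco1 was 2.74-fold and Ndrg4 2.47-fold lower. In each of these genes all 5 tamoxifen-labelled values lay on one side of the 5 vehicle-labelled ones, and the highest limma adjusted p among them was 8.79e-05.

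**Figure D3:**
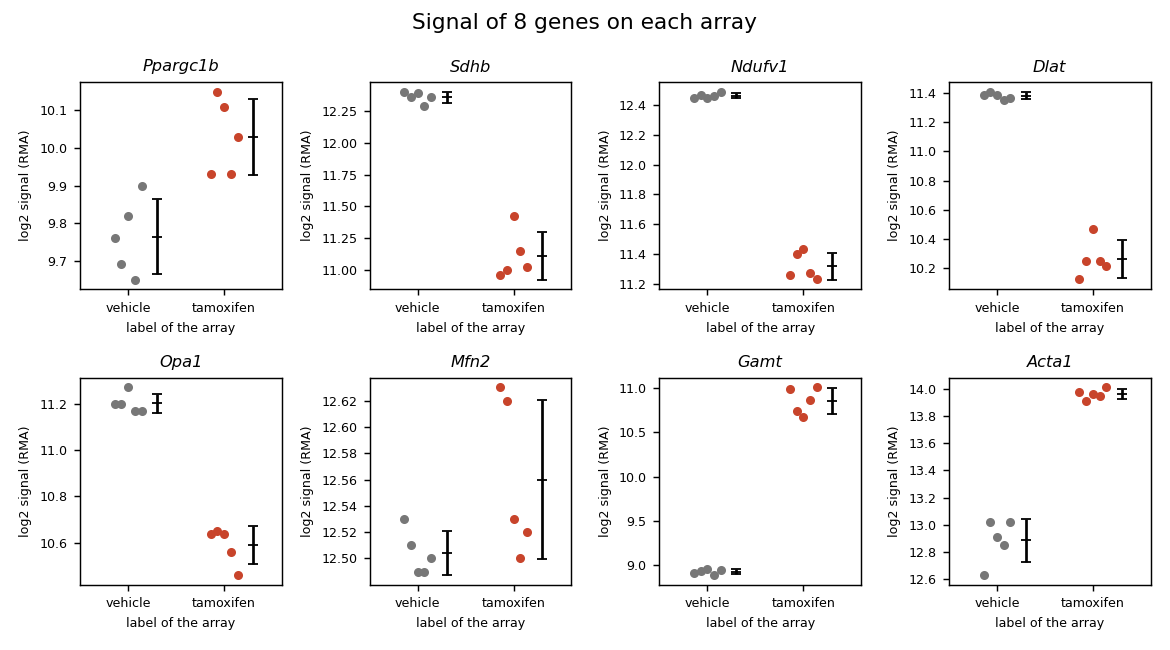
Each point is the log2 RMA signal of 1 gene on 1 array, with 5 vehicle-labelled (grey) and 5 tamoxifen-labelled arrays (red), and the bar beside them is the mean ± SD; the vertical axes do not start at 0. Sdhb, Ndufv1, Dlat and Opa1 are lower and Ppargc1b, Gamt and Acta1 higher on all 5 tamoxifen-labelled arrays, while the values of Mfn2 overlap (means 12.50 and 12.56).

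Markers of some other cell types rose and of others did not. Of 18 macrophage markers, 14 rose (17 adjusted over the list alone, list adjusted p = 1.63e-07, adjusted p = 0.285 with an estimated correlation), including Cd68 (0.40 ± 0.071) and Mrc1 (0.30 ± 0.065). Of 15 fibroblast markers, 8 rose (10 adjusted over the list alone, list adjusted p = 0.00166, adjusted p = 0.373 with an estimated correlation), including Mfap5 (0.44) and Pi16 (0.24). Of 34 genes of the extracellular matrix, 21 rose and 0 fell (25 higher adjusted over the list alone, mean 0.27, adjusted p = 9.19e-09), and the adjusted p was 0.277 with an estimated correlation. Thbs1 rose by 0.85 ± 0.093 and the collagen gene Col8a1 by 0.59 ± 0.071. Skeletal muscle markers passed (adjusted p = 0.0216; 4 of 9 higher and 4 adjusted over the list alone), led by Acta1, Myl1 (0.59) and Ckm, which the heart also makes. That adjusted p was 0.373 with an estimated correlation and 0.0620 without tamoxifen array 3 (0.000872 to 0.373 over all alternatives). Endothelial markers did not pass (mean 0.017, median -0.0010, adjusted p = 0.785), with 1 of 14 higher, Cldn5 at 0.35 (1 adjusted over the list alone). Cldn5 lost its call without vehicle array 4 and tamoxifen array 2 together, an alternative chosen after seeing the data (0.31, adjusted p = 0.0614, range 0.000551 to 0.0614 over all alternatives). Smooth muscle and pericyte markers (adjusted p = 0.349; 2 of 12 higher, 2 adjusted over the list alone, with Cnn1 at 0.34) and mesothelial markers (adjusted p = 0.770; 1 of 7 higher, 1 adjusted over the list alone, Krt18 at 0.47) did not pass either.

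The other markers also stayed short of the threshold. Adjusted p was 0.127 for lymphocytes (0 of 4 called, 2 lower adjusted over the list alone), 0.729 for nerve (0 of 5 called, 0 adjusted over the list alone) and 0.661 for lung and thymus (0 of 4 called, 0 adjusted over the list alone). Adipocyte markers gave 1 higher and 1 lower of 7, the same counts adjusted over the list alone, with an adjusted p of 0.770. Atrial markers gave 3 higher and 2 lower of 13 (3 and 2 adjusted over the list alone, list adjusted p = 0.442). Granulocyte and erythroid markers had 2 tested members each and were not tested as lists. The female-specific transcript Xist read between 11.55 and 11.82 on all 10 arrays.

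Of 25 p53 and DNA damage genes, 12 rose and 1 fell (12 and 1 adjusted over the list alone, mean 0.14, adjusted p = 0.00562), and the adjusted p was 0.342 with an estimated correlation. Its leading members were Btg2 (0.81 ± 0.079) and Plk3 (0.49 ± 0.065), which many stimuli induce within minutes, and Perp (0.38 ± 0.045). Cell cycle genes passed with all arrays (adjusted p = 0.0362; 3 of 18 higher, 2 adjusted over the list alone; Pcna at 0.27), with an adjusted p of 0.515 with an estimated correlation. Without vehicle array 1 or 2 or tamoxifen array 2 the cell cycle list gave an adjusted p of 0.0569, 0.0548 and 0.0691 (0.000487 to 0.515 over all alternatives). Circadian clock genes did not pass with all arrays (adjusted p = 0.142; 3 of 16 higher, 1 adjusted over the list alone; Bhlhe40 at 0.35), but did without vehicle array 1 (adjusted p = 0.0456; 0.0381 to 0.514 over all alternatives). Hypoxia and angiogenesis genes did not pass (adjusted p = 0.282; 3 higher and 2 lower of 18, the same adjusted over the list alone), with Angpt1 at -0.83 ± 0.062 and Vegfb at -0.39 ± 0.050. Genes that respond to the oestrogen receptor, which tamoxifen binds, did not pass (adjusted p = 0.534; 2 of 10 higher, 2 higher and 1 lower adjusted over the list alone; Mybl1 at 0.62). Interferon response genes did not pass (adjusted p = 0.785; 1 of 24 lower, 0 adjusted over the list alone). In all, 9 lists were higher, 16 lower and 20 not past the threshold, and 8 passed with an estimated correlation. These are not counts of independent results, since lists share genes. Oxidative phosphorylation enters as the list of each complex and again as their union. The PPAR list shares genes such as Acadvl and Hadha with fatty acid oxidation. Per the source names, vehicle-injected mice had no tamoxifen, which switches MerCre on, and Cre activity was not measured here. The effects of tamoxifen, Cre activity and deletion therefore cannot be told apart between the groups. Neither scan dates nor sex are given in the labels, although Xist and the Y-linked genes read as female on every array.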

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

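The tests of chance splits and of the hour of collection were set before their result was seen. All other tests of explanations here were chosen for that use only after the result was seen. The quantile normalization was itself set before the data were examined, and only its use against a shift of whole arrays came later. Of 100 splits of the 10 arrays into 5 and 5, out of 126 possible, 1 gave as many genes as the real split, the real one itself. It gave 3059 genes and the highest of the others 1. The other splits keep the difference between the labels within their groups, which widens their spread and lowers their counts. The size of the gap is therefore no measure of chance, and a first rank among 100 is the most this test can show.

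The mean of the oxidative phosphorylation genes fell in the tamoxifen-labelled arrays. A smaller share of heart muscle RNA could lower them, but would lower the sarcomere genes made by the same cells as well. These had a median log2 fold change of 0.072 (SD over genes 0.167) against -0.62 in the respiratory genes. The values argue against a smaller share as the source of the whole fall. A smaller part is not excluded, since the sarcomere list passed as higher under some alternatives and a rise could hide a loss. A bias that depends on brightness could act on bright genes as a class, but of 10000 random lists matched on signal the lowest median was -0.006. The middle one of these medians was 0.056, so genes as bright as the respiratory ones lay slightly above 0 as a class. The sarcomere median of 0.072 is near that value, and no lists matched to the sarcomere genes were drawn. The effect of tamoxifen or of Cre by itself cannot be told apart from that of the deletion, since 0 arrays had tamoxifen without the deletion. The deletion of PGC-1β named in the labels stays open too, as does binding of the probes to pseudogene transcripts, which was not tested.

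Immediate early genes, transcription factors and others induced within minutes of a stimulus, were higher in the tamoxifen-labelled arrays: 20 of 31 rose (mean log2 fold change 0.45; adjusted p = 3.78e-12 and 0.0443 with an estimated correlation, with Btg2 and Atf3 also in fixed lists). The family was chosen with Nr4a3, Egr1, Nr4a1, Btg2 and Atf3 already seen, and without these 5 members 15 of 26 rose (mean 0.32, adjusted p = 2.52e-08, and 0.0531 with an estimated correlation, not past the threshold). Rough handling of single animals could raise them, but the lowest tamoxifen-labelled array lay 0.329 above the highest vehicle-labelled one, with a larger SD within a group of 0.0978, and for the 26 members alone this gap was 0.192 and the SD 0.0927. A different hour of collection could raise them too, but with the phase of the clock genes in the model the difference was 0.449 ± 0.053 (SE), against 0.452 without it (0.313 ± 0.048 against 0.317 for the 26). This phase index was the mean of Dbp, Tef, Hlf, Per2, Per3, Nr1d2 and Bhlhe41 less that of Arntl and Clock. It read 0.48 ± 0.51 in the vehicle-labelled and 0.36 ± 0.49 in the tamoxifen-labelled arrays (SD, n = 5). A single linear index can read alike at different hours, so a difference in hour that it misses is not excluded. Handling that differed between the groups as a whole stays open, as does the stress of a ventricle with fewer respiratory transcripts; neither was tested.

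Ppargc1b read higher where the labels state its deletion. An upward shift of whole arrays could raise it, but after quantile normalization the rise was 0.24 (adjusted p = 0.00640; 0.000502 to 0.0222 over all alternatives). Exchanged labels of single arrays could raise it as well, but the lowest vehicle-labelled array lay 0.529 above the highest tamoxifen-labelled one in the mean of the oxidative phosphorylation genes (larger SD within a group 0.0642); an exchange of all 10 labels together would leave this value as it is and stays open. Probes outside the deleted exons, which may read a shortened transcript, stay open, since the gene had 1 probe set and no values of single probes were used.

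A single array lay far from the other 4 of its group in 25 of 314 groups of values examined; chance alone does this in about 1 in 20 groups. Each value is given against the nearest of the other 4. On the tamoxifen-labelled array 2 this was the median of all probe sets (7.31 against 7.20), and high values of Akip1 (9.81 against 9.59), Mfap5 (11.02 against 10.73), Taz (9.70 against 9.57) and Cox6a2 (13.38 against 13.27). The same array had high mean signals of the PGC-1 family (9.87 against 9.63), mitochondrial chaperones and proteases (10.48 against 10.38), p53 and DNA damage genes (8.71 against 8.60), cell cycle genes (7.67 against 7.45), smooth muscle markers (9.74 against 9.60) and adipocyte markers (8.11 against 7.98). On the tamoxifen-labelled array 3, Txn2 was high (10.97 against 10.84) and Thbs1 (9.48 against 9.82) and Cldn5 (9.65 against 10.06) were low. Bhlhe40 was low on tamoxifen-labelled array 1 (9.38 against 9.51) and Coq9 on array 5 (11.09 against 11.32). Vehicle-labelled array 2 had a high Pprc1 (7.78 against 7.53), a low Eno3 (13.46 against 13.49) and high macrophage markers (8.61 against 8.46). Pgam2 was high on vehicle-labelled array 3 (11.58 against 11.46) and Vegfb low on array 5 (11.55 against 11.62). Vehicle-labelled array 4 had low glycolysis genes (11.42 against 11.46) and hypoxia genes (9.96 against 10.03), and high lymphocyte (7.33 against 7.11) and lung and thymus markers (7.17 against 7.06).

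Probe sets without a gene name were not used in the comparison. Of 6243 of them bright enough to be tested, 119 were lower and 95 higher in the tamoxifen-labelled arrays (limma adjusted p of 0.05 over these). The 30 of them with the lowest identifiers had a median log2 fold change of -0.18, all 30 were negative and 9 passed, with means of 9.75 ± 0.061 and 9.50 ± 0.056 (SD, n = 5 per group). They were singled out after their values were seen, so no test is given. What these 30 measure is not given in the annotation used.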

How the results depend on the processing

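The tests without vehicle array 4 and tamoxifen array 2 together, those without 5 immediate early genes, and those of the families named in the last part, were chosen only after the result was seen. Of the gene counts, Ppargc1b and the main list tests under all alternatives, 249 values kept their direction and their side of the threshold or stayed within 1.5 times, 3 were no longer past the threshold, 2 counts moved by more and 0 reversed. The 2 counts were 1780 lower genes with array weights and 5 instead of 19 other lists with an estimated correlation. The 3 were fatty acid oxidation (-0.24; adjusted p = 0.135), mitochondrial dynamics (-0.33; 0.0655) and the mitochondrial ribosome (-0.28; 0.0510) with an estimated correlation; the alternative leaves the mean as it is and widens its error, and for the count of 1780 the cause was not tested. With each array left out in turn, genes higher ranged from 1493 to 1960, genes lower from 940 to 1646, the oxidative phosphorylation mean from -0.66 to -0.62, the heart failure mean from 0.41 to 0.46 and Ppargc1b from 0.24 to 0.30. With the replicate number as a block, 2232 genes were higher and 1300 lower. The labels state no pairing, so the main fit had no block. Correlations by number were 0.175, 0.203, 0.0981, 0.0390 and 0.174, all positive though not all above 0.1. Of 10 arrays, 7 correlated best with their own number, which is 1 of 5 possible partners for each. A pairing by number therefore stays open. Under the block, ketone body use was not past the threshold (adjusted p = 0.0629; 0.000355 to 0.345 over all alternatives) and the circadian clock was (0.0381; 0.0381 to 0.514). No other list or named gene changed its call under the block. Of the other lists and families, 949 values stayed as they were, 40 were no longer past the threshold, 19 newly past it and 19 reversed; of the named genes 2171, 12, 8 and 4. All that reversed were near 0 and not called: endothelium (-0.00334 with array weights, -0.0128 with quantile normalization, -0.0189 with both arrays left out), interferon response (0.00483) and adipocytes (0.00371) with centred arrays, and cardiolipin synthesis (-0.0104) with both arrays left out. With 1 array left out these were, as ranges, interferon response -0.0357 to 0.0311, Ndufaf2 -0.0490 to 0.0195, adipocytes -0.0342 to 0.0291, nerve -0.0364 to 0.00800, lung and thymus -0.0345 to 0.00488, endothelium -0.00886 to 0.0365 and atrial markers -0.0832 to 0.00796; the cause was not tested. Signal over background limits what can be said of the 6069 genes at or under the log2 cutoff of 6.55.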

Other observations

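The families in this part, the tests on them and the genes named from them were chosen only after the result was seen. Their adjusted p corrects for the added families alone and not for that choice, so it overstates the support. Further mitochondrial families were lower in the tamoxifen-labelled arrays. Of 7 complex I assembly factors, 4 fell (mean log2 fold change -0.35, adjusted p = 5.66e-06 and 0.0443 with an estimated correlation). This restates part of the complex I result, since 4 of the 7, and 3 of the 4 that fell, also belong to the fixed complex I list. Of 12 genes of coenzyme Q synthesis, 6 fell and 2 rose (mean -0.24, adjusted p = 1.84e-04 and 0.0762 with an estimated correlation), with Coq5 at -1.05 ± 0.069 (SE, n = 5 per group) and Coq9 at -0.66 ± 0.063. Of 16 mitochondrial aminoacyl-tRNA synthetases, which charge the transfer RNAs used inside mitochondria, 8 fell (mean -0.17, adjusted p = 6.75e-06 and 0.0705 with an estimated correlation).

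The chosen families of immediate early genes, heat shock proteins and cytosolic ribosomal proteins were higher. This does not hold for the cytosol and nucleus in general. Of the fixed lists, glycolysis had 7 genes higher and 4 lower, and metabolic transcription factors had 1 higher and 6 lower. Among the immediate early genes, Fos rose by 0.90 ± 0.11, Egr2 by 0.85 ± 0.090 and the growth factor gene Hbegf by 0.79 ± 0.094 (SE, n = 5 per group), beside Egr1, Nr4a1 and Nr4a3. Of 21 heat shock protein genes, 11 rose (mean 0.21, adjusted p = 2.40e-05 and 0.0531 with an estimated correlation), including the chaperone genes Hspa1a (0.85 ± 0.14) and Hsp90aa1 (0.44 ± 0.068). Of 54 cytosolic ribosomal protein genes, 32 rose and 0 fell (mean 0.19, adjusted p = 2.31e-12 and 0.0531 with an estimated correlation), in the same arrays in which 47 of 73 mitochondrial ribosomal genes fell. None of these families changed direction under any alternative run.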
